A study of Lachancea kluyveri with 9 samples.

How the data were processed

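Poly(A) RNA was sequenced from cultures of the budding yeast Lachancea kluyveri in 3 cell types, with 3 libraries each. The a cells (strain yLB76) and the alpha cells (strain yLB77) are the haploid mating types, and the a/alpha cells (strain FDy22) carry both mating-type alleles. Per the labels' protocols, cultures were diluted to an optical density of 0.1 in 10 mL of YPED medium at 30 °C and grown to between 0.5 and 1. Libraries were made with a directional (strand-marking) kit and sequenced as single reads of 65 bp. The column headers call the libraries biological replicates. Each cell type was a single strain, so differences between strains and between cell types fall together.

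The authors deposited a table of read counts for 5189 gene models on 8 chromosomes. Per the file headers, reads over coding parts (CDS) were counted with featureCounts 2.0.1 using strand setting 1, and the paths of the alignments name fastp and STAR. The command names 14 alignments, of which 5 are not analysed here. The genome build is not given in the sources used here, and coordinates are those of the deposited table. The table also gives each model's summed coding length in bp.

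The authors also deposited 2 tables of comparisons, each with a mean signal over libraries, a log2 fold change with its error, a test score, a p-value and an adjusted p-value. The submitters' processing notes name DESeq2, and give no design. In these deposited tables, 3 models with 0 counts in all 9 libraries have a mean signal above 0, so the mean signal was not computed from these 9 libraries alone.

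The files pair no gene name with the model identifiers. The 24 lists of Saccharomyces cerevisiae genes fixed before the data were examined matched 0 models, and the planned gene list tests and named list members were not run. Genes are given here by position, and at most 2 identifiers of higher and 2 of lower models are printed.

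Library totals ran from 743244 counts (a/alpha replicate 1) to 10776548 (a/alpha replicate 2), and the other libraries lay at or above 6379488. A count of 3 corresponds to 4.04 CPM (counts scaled to library size) in a/alpha replicate 1 and to 0.278 CPM in a/alpha replicate 2. Such limits cover counting error only. Replicates of a group differed by more than sampling noise, with chi-square per degree of freedom between 4.76 and 82.9, and no library was a duplicate.

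Counts were fitted with edgeR 4.0.16 in R 4.3.3. The fit used all 9 libraries, TMM factors, the filterByExpr filter and quasi-likelihood tests with Benjamini-Hochberg adjustment at 0.05. It kept 5042 models, and the 147 left out held 0.0051% of the counts. TMM factors lay between 0.809 and 1.16, and the biological coefficient of variation was 18.0%. Standard errors of log2 fold changes were taken as the fold change divided by the root of the F statistic, which is approximate. CPM values use the TMM factors and are given as mean ± SD over 3 libraries.

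A model was placed in a class when both of its pairwise comparisons passed the threshold with a fold change of at least 2 in the named direction. Models given in the text were taken from the top of lists of 10. Each list held models past the threshold whose 3 libraries of 1 group all lay above those of the other, ranked by fold change. Classes were ranked by the smaller of the 2 fold changes. Chance alone separates 3 libraries from 3 others in 10.0% of models. Models named outside this rule are said to be chosen after their values were seen.

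Replicate numbers were checked for pairing by correlating deviations from group means across models. For a and alpha libraries the correlations were 0.75, 0.22 and 0.55 for numbers 1, 2 and 3, all above the limit of 0.1, so these numbers were taken to pair them. Number 2 was 0.14 outside the first 1 Mb of chromosome C, and its libraries did not correlate best with their own number. Deviations within a group are tied by their shared mean, so these correlations are not independent of each other. The labels do not say what the numbers share, and the main fit did not use the pairing. For comparisons with a/alpha cells the numbers did not pair the libraries.

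On simulated counts for 5042 models, with 100 changed 2-fold and 100 changed 4-fold, up or down, in both haploid types alike, the a against a/alpha test recovered 77.0% and 97.0%. The alpha against a/alpha test recovered 72.0% and 97.0%. These tests made 7 and 8 false calls. The simulation drew each model on its own and left out trends that many models share within a library, so rates in the real data may differ.

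Alternatives fixed before the data were examined were other size factors, other filters, DESeq2 1.42.0, fits of 2 groups alone, a replicate block, other thresholds and leaving out each library. Alternatives chosen after seeing the data left out the first 1 Mb of chromosome C, took its level as a covariate, left out models overlapping another on the opposite strand, or blocked the a and alpha libraries alone. Figures were drawn with matplotlib 3.10.9.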

Results

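RNA levels of 5189 gene models were measured in a, alpha and a/alpha cells of Lachancea kluyveri, 3 libraries per cell type. The series concerns haploid-specific genes, which in budding yeasts are transcribed in both mating types and repressed in a/alpha cells by a heterodimer of the mating-type proteins. The a libraries held 6379488, 6502834 and 8908799 counts in replicates 1, 2 and 3. The alpha libraries held 6929356, 7921388 and 8675311 counts, and the a/alpha libraries 743244, 10776548 and 9164901. Within a cell type, log2 CPM correlated across models by 0.957 to 0.991.

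The first question was which genes were transcribed in both haploid types and held low in a/alpha cells. A set of 80 models was at least 2-fold higher in both a and alpha cells than in a/alpha cells. The class rests on fold changes and sets no limit on the level itself. Mean levels of its members in a/alpha cells ran from 0.067 to 436 CPM. Their median level was 61.4 CPM in a cells, 40.8 in alpha cells and 9.91 in a/alpha cells. The 80 models took 2.68% ± 0.021 of all counts in a cells (SD, n = 3), 1.29% ± 0.14 in alpha cells and 0.20% ± 0.029 in a/alpha cells. Of these models, 32 were at least 4-fold and 11 at least 16-fold higher in both haploid types, and 7 lay under 1 CPM in a/alpha cells.

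The model with the highest rank in this class lay on the minus strand of chromosome G from 1653751 to 1655106 (augustus_masked-SAKL0G-processed-gene-16.177). It was at 142 ± 13.6 CPM in a cells, 130 ± 17.8 in alpha cells and 2.01 ± 0.62 in a/alpha cells (SD, n = 3). Its log2 fold changes against a/alpha cells were 5.95 ± 0.23 (SE) in a and 5.82 ± 0.23 in alpha cells. The adjusted p-values were 3.32e-09 and 1.51e-08 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment.

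A minus-strand model on chromosome B from 410581 to 411792 was at 426 ± 144 CPM in a, 286 ± 61.9 in alpha and 9.59 ± 1.71 in a/alpha cells. Its neighbour from 412711 to 413379, lower in rank and chosen after its position was seen, was at 261 ± 52.2, 295 ± 36.3 and 13.6 ± 3.43 CPM. Another chromosome B model, on the plus strand from 512549 to 513643, was at 58.7 ± 16.9 CPM in a, 47.8 ± 4.79 in alpha and 3.10 ± 2.07 in a/alpha cells. On chromosome H, the model from 1736625 to 1737671 was at 278 ± 31.9 CPM in a, 241 ± 7.79 in alpha and 13.1 ± 2.69 in a/alpha cells. A pair of models of similar rank on chromosome C, from 541385 to 541675 and from 228916 to 229903, overlap models on the opposite strand, which makes their counts uncertain. The models they overlap, from 539308 to 542772 and from 229684 to 230997, are members of the class too. In all, 6 of the 80 models overlap another model on the opposite strand. The most abundant member, chosen after its values were seen, was a model on chromosome D from 991105 to 992754. It stood at 7835 ± 920 CPM in a, 6939 ± 884 in alpha and 436 ± 205 in a/alpha cells.

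**Figure D1:**
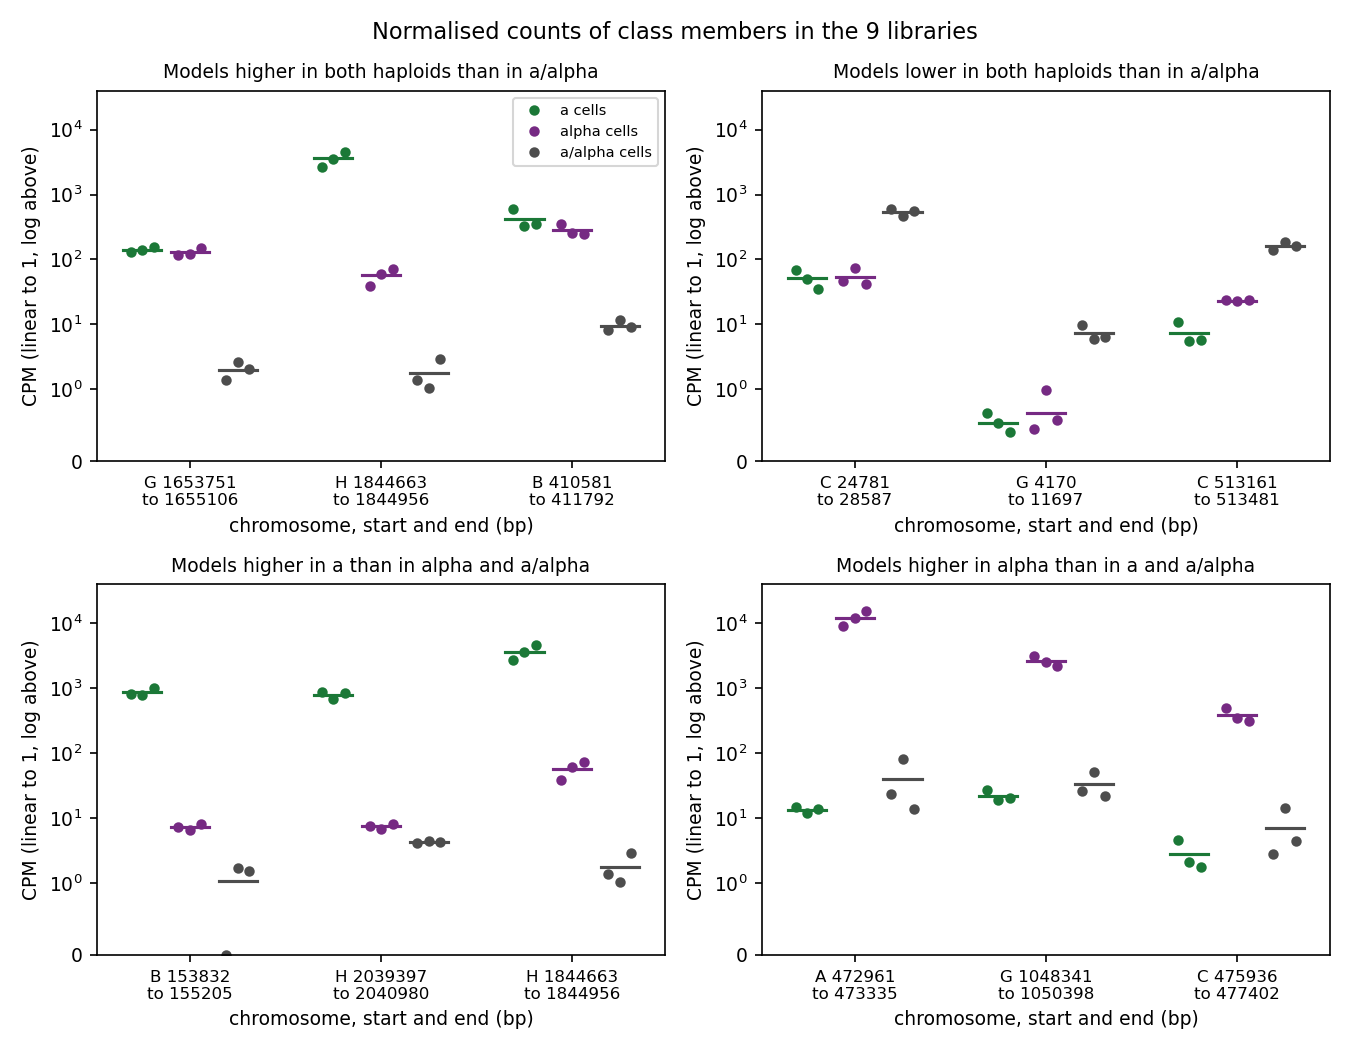
Normalised counts in CPM (vertical axis, linear to 1 and logarithmic above) of 3 models from the top of each of the 4 classes, leaving out models that overlap another on the opposite strand. Points are single libraries and lines are group means, which for the chromosome G model from 1653751 to 1655106 were 142 CPM in a, 130 in alpha and 2.01 in a/alpha cells.

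Members of the class differed between the haploid types: 25 of the 80 models were higher in a than in alpha cells, 4 were higher in alpha cells, and 51 did not pass the test. The short model on the minus strand of chromosome H from 1844663 to 1844956 (augustus_masked-SAKL0H-processed-gene-18.122) has 294 bp of coding length. It was at 3593 ± 945 CPM in a cells, 57.0 ± 17.0 in alpha cells and 1.77 ± 1.00 in a/alpha cells. Coding lengths under 400 bp were found in 19 of the 80 models and in 7.85% of all tested models. The class held 13 models from the first 1 Mb of chromosome C, or 16.2% against 8.91% of tested models (two-sided Fisher's exact test, p = 0.0281, adjusted 0.112 over the 4 classes tested), which did not pass the correction. In that region levels also differed between libraries of 1 cell type. The 13 models include the overlapping chromosome C models and the models they overlap, whose counts are not independent.

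In the opposite direction, 27 models were at least 2-fold lower in both haploid types than in a/alpha cells. Their median was 13.8 CPM in a, 12.9 in alpha and 49.4 in a/alpha cells. The first by rank lay on chromosome C from 24781 to 28587 (augustus_masked-SAKL0C-processed-gene-0.20), at 51.5 ± 17.0, 54.3 ± 17.5 and 536 ± 65.9 CPM. Its log2 fold changes were -3.38 ± 0.28 in a and -3.30 ± 0.28 in alpha cells. The model from 513161 to 513481 on the same chromosome (augustus_masked-SAKL0C-processed-gene-5.23) was at 7.42 ± 3.08 CPM in a, 23.2 ± 0.52 in alpha and 164 ± 23.9 in a/alpha cells. Another on chromosome G from 4170 to 11697 was at 0.539 ± 0.134, 0.673 ± 0.286 and 7.32 ± 2.00 CPM. The class held 8 models on chromosome A and 6 each on chromosomes B and C. Of its models 5 lay in the first 1 Mb of chromosome C, or 18.5% against 8.91% of tested models (two-sided Fisher's exact test, p = 0.0863, adjusted 0.173), which did not pass. Without a replicate 1 it held 43 models in place of 27.

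The a against a/alpha comparison asks which RNA levels differ between a cells and a/alpha cells. The chromosome H model from 1844663 to 1844956 rose most, with a log2 fold change of 10.88 ± 0.46, or 11.72 without a/alpha replicate 3. A plus-strand model on chromosome B from 153832 to 155205 rose by 9.14 ± 0.29, from 1.06 ± 0.92 CPM in a/alpha to 866 ± 132 in a cells. Another, on chromosome H from 2039397 to 2040980, rose by 7.52 ± 0.22, from 4.24 ± 0.15 to 788 ± 106 CPM. In the shallow a/alpha replicate 1 these models stood, in this order, at 1.37, 0 and 4.12 CPM. There 3 counts equal 4.04 CPM before the library's TMM factor of 0.98 is applied, and slightly more after it. Their spread in a/alpha cells is therefore poorly known. Among lower models, the chromosome C model from 513161 to 513481 changed by -4.49 ± 0.25 and a chromosome B model from 126269 to 127114 by -4.40 ± 0.28. In all, 652 of 5042 models passed edgeR's quasi-likelihood test, 369 higher and 283 lower in a cells. At least 2-fold changes were seen for 193 higher and 66 lower models. DESeq2 called 404 higher and 417 lower. The count was 1075 without a replicate 1, 334 without a replicate 2 and 414 without a replicate 3, and 352 and 351 without a/alpha replicates 2 and 3.

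The alpha against a/alpha comparison asks the same of alpha cells. A short plus-strand model on chromosome A from 472961 to 473335 rose most, by 8.15 ± 0.61 on the log2 scale, or 9.56 without a/alpha replicate 2. It was at 12040 ± 3120 CPM in alpha cells against 13.3 ± 1.31 in a cells, and at 23.3, 81.1 and 13.5 CPM in a/alpha replicates 1, 2 and 3. The chromosome G model from 1048341 to 1050398 rose by 6.24 ± 0.34, to 2602 ± 485 CPM from 32.8 ± 15.9, and by 6.84 without a/alpha replicate 2. The lowest by fold change was a chromosome A model from 930346 to 931182, at -4.18 ± 0.37, followed by the opposite-strand model it overlaps, from 930830 to 931132, at -3.92 ± 0.39, and both are uncertain. The chromosome C model from 350495 to 351358 changed by -3.53 ± 0.25. In all, 517 models passed the test, 330 higher and 187 lower in alpha cells, and 146 and 86 of them changed at least 2-fold. With upper-quartile size factors the split was 268 higher and 290 lower, and DESeq2 called 831 models and a fit of these 2 groups alone called 920. The count was 1172 without a replicate 1, 983 without alpha replicate 1, 218 and 196 without alpha replicates 2 and 3, and 152 and 182 without a/alpha replicates 2 and 3.

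**Figure D2:**
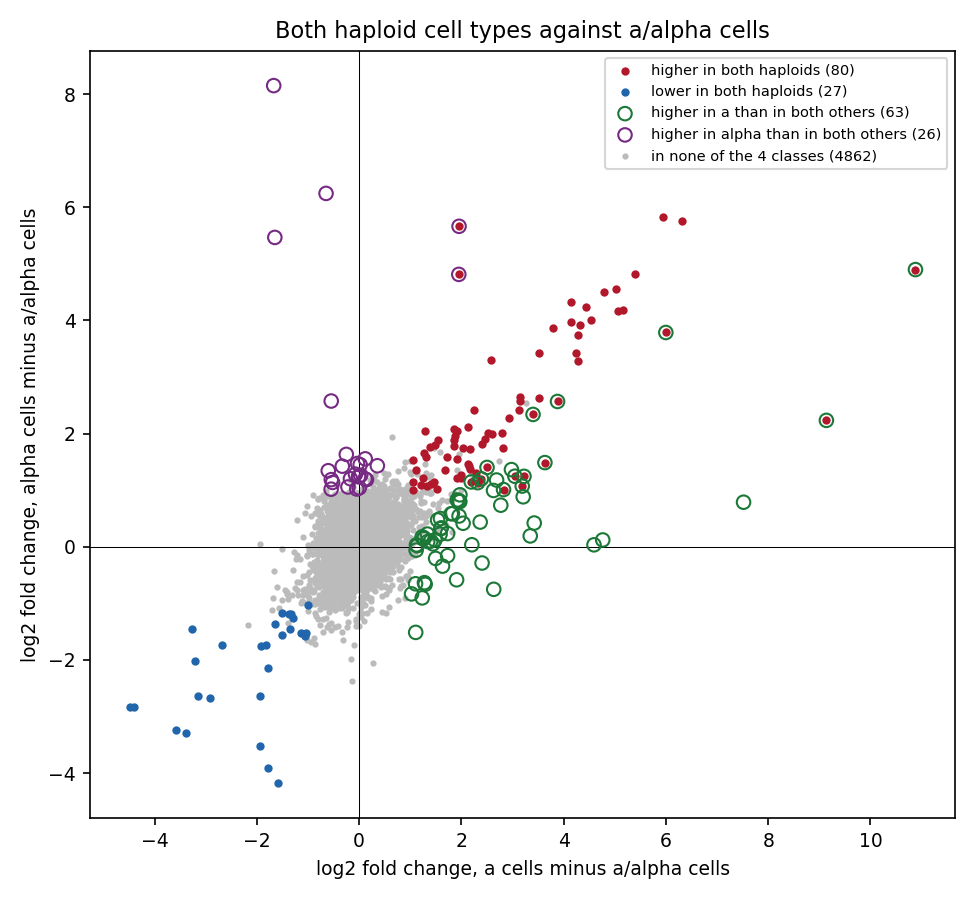
Log2 fold changes against a/alpha cells of 5042 tested models in a cells (horizontal axis) and alpha cells (vertical axis), with the 4 classes coloured. The 80 models higher in both haploid types lie at the upper right and the 27 lower ones at the lower left, and rings mark the 63 a and 26 alpha class models.

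Both comparisons called 203 models in the same direction, 136 higher and 67 lower, and 13 in opposite directions. Simulated groups with shared a/alpha libraries and no changed model gave 0 in 100 draws, which leaves out the effects. Independent lists would share 24.2 higher and 10.5 lower, which leaves out the shared libraries. The fold changes correlated by 0.57 across models (Spearman's rho 0.38) against 0.54 in the simulation, and models are not independent replicates. No rho was computed in the simulation. Their covariance was 0.234 against a simulated 0.0327, a difference of 0.201. Covariance grows with the size of the changes, so this difference can rest on a few models with large ones. The simulation left out what paired a and alpha libraries share, for which the estimated covariance was 0.018. With 3 a/alpha libraries the controls could not be divided, so part of the excess in calls may come from the shared libraries. The count of 203 was 506 without a replicate 1, 115 and 126 without alpha replicates 2 and 3, and 91 and 102 without a/alpha replicates 2 and 3. The count of 13 was 26 without a replicate 1 or alpha replicate 1, 5 and 7 without a replicates 2 and 3, 4 and 6 without alpha replicates 2 and 3, and 2 and 4 without a/alpha replicates 2 and 3.

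The a against alpha comparison asks what distinguishes the mating types. A set of 63 models was at least 2-fold higher in a cells than in both others, and 14 of them also belong to the 80 above. The first by rank was the chromosome B model from 153832 to 155205, at 7.21 ± 0.79 CPM in alpha cells. The chromosome H model from 2039397 to 2040980 was at 7.40 ± 0.66 CPM in alpha cells. A chromosome A model from 894334 to 898263 was at 559 ± 40.7 CPM in a cells against 22.3 ± 3.94 in alpha and 19.97 ± 1.90 in a/alpha cells. A chromosome F model from 524553 to 528101 was at 169 ± 34.5, 7.11 ± 2.37 and 7.32 ± 1.18 CPM.

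A set of 26 models was at least 2-fold higher in alpha cells than in both others. The chromosome A model from 472961 to 473335 and the chromosome G model from 1048341 to 1050398 led it. The chromosome C model from 475936 to 477402 was at 385 ± 98.4 CPM in alpha, 2.82 ± 1.56 in a and 7.09 ± 6.15 in a/alpha cells. Its log2 fold change against a/alpha cells was 5.47, and 6.52 without a/alpha replicate 2. An overlapping pair on chromosome E, from 388024 to 389459 and from 389294 to 389977, belongs both here and to the 80 models above. The class took 1.80% ± 0.18 of counts in alpha cells, 0.216% ± 0.036 in a cells and 0.209% ± 0.040 in a/alpha cells. Much of the share in alpha cells came from the chromosome A model, at 12040 CPM there against a class median of 191 CPM. The class held 59 models without alpha replicate 1, 16 without alpha replicate 3, and 49 and 15 without a/alpha replicates 1 and 2.

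Between a and alpha cells, 905 models passed edgeR's quasi-likelihood test, 406 higher and 499 lower in a cells, and 135 and 148 of these changed at least 2-fold. With a replicate block, which pairs libraries of the same number, 1575 models passed. With upper-quartile size factors the split was 630 higher and 369 lower, and the median log2 fold change of all models moved from 0.05 to 0.17. The count was 588 without a replicate 2, and 486 and 427 without alpha replicates 2 and 3.

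Levels along the first 1 Mb of chromosome C moved together within single libraries. The region was set after these levels had been seen, and this arm of the L. kluyveri genome is known for a higher GC content than the rest. Over 402 models, the median log2 deviation from the mean of the 9 libraries was 0.64, -0.33 and -0.26 in a replicates 1, 2 and 3. It was 0.10, -0.43 and -0.49 in alpha and 0.31, 0.28 and 0.19 in a/alpha libraries. Group means were 0.02 ± 0.54 in a, -0.27 ± 0.32 in alpha and 0.26 ± 0.06 in a/alpha cells (SD, n = 3). Exact two-sided permutation tests gave p = 0.4 for a and p = 0.1 for alpha against a/alpha, and p = 0.5 for a against alpha (n = 3 per group), where 0.1 is the smallest p this design allows. With a and alpha libraries paired by number, a was higher by 0.54, 0.10 and 0.24, and the exact sign-flip test gave p = 0.25 (n = 3 pairs), the smallest it can give. Adjusted over these 4 exact tests the values were 0.5, 0.4, 0.5 and 0.5, so a difference is neither shown nor ruled out.

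**Figure D3:**
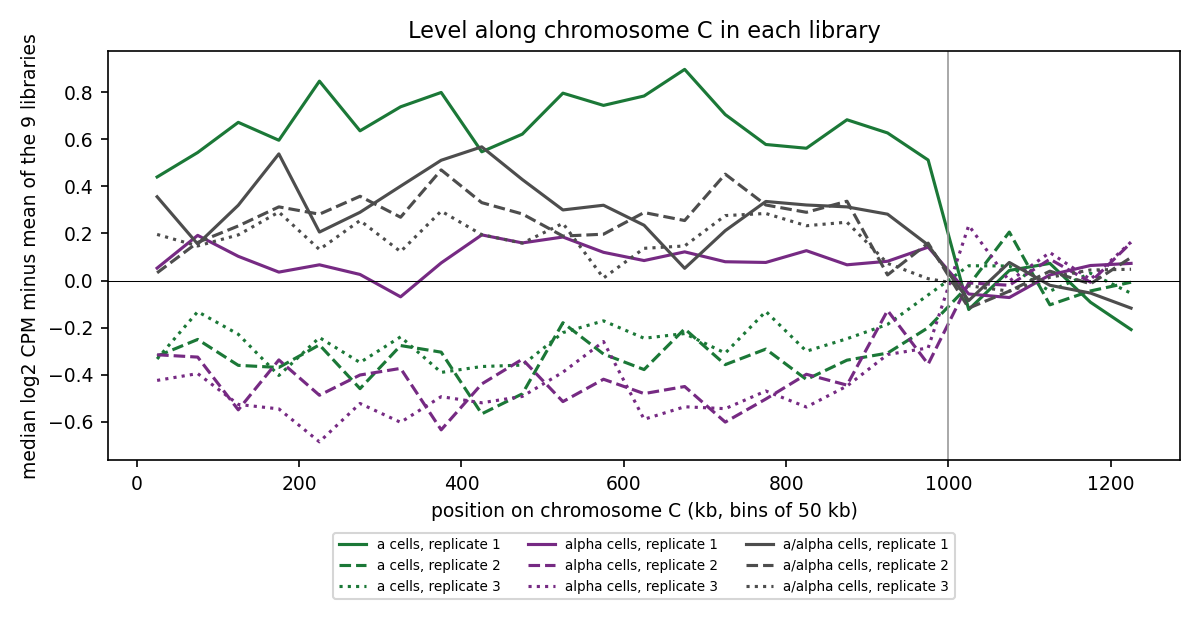
Median log2 CPM minus the mean of the 9 libraries (vertical axis) in bins of 50 kb along chromosome C (horizontal axis, kb), 1 line per library. In the first 1 Mb, a replicate 1 has a median of 0.64 and alpha replicate 3 of -0.49, and the vertical line marks the end of this region.

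In the authors' deposited tables, 692 models passed an adjusted p of 0.05 for a against a/alpha (362 higher, 330 lower) and 558 for alpha against a/alpha (320 higher, 238 lower). The edgeR test called 578 and 436 of these models of the authors' deposited tables in the same direction, or 83.5% and 78.1%, and 0 in the opposite direction. Log2 fold changes of the authors' deposited tables and of the edgeR fit correlated by 0.999 across 5042 models in both comparisons. By the same rule of 2-fold in both comparisons, the authors' deposited tables hold 79 higher models, 77 of them among the 80, and 31 lower models, which include all 27. These matches compare ways of processing the same series and are not independent evidence for the calls.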

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

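The tests of chromosome C, of nested models and of neighbouring models were chosen after the results were seen. So were the counts over the splits of all classes together, over splits by pairs and over exchanges within numbers. The counts over 100 splits of all libraries and over the splits of each pairwise comparison were planned. No test of single outlying libraries was applied to groups of 3, and libraries differed in both haploid types. Chi-square per degree of freedom was 57.3 and 77.7 between a replicate 1 and a replicates 2 and 3 and 13.8 between those, and in alpha cells 37.1 (replicates 1 and 2), 82.9 (1 and 3) and 33.9 (2 and 3).

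The effects of the 2 haploid types relative to a/alpha cells differed for 29 of the 80 models higher in both, by the a against alpha test itself. The largest differences (log2, a minus alpha) were 6.90 for the chromosome B model from 153832 to 155205 and 5.98 for the chromosome H model from 1844663 to 1844956. On the alpha side they were -3.71 and -2.86 for the overlapping chromosome E models from 389294 to 389977 and from 388024 to 389459. Another 13 models changed in opposite directions in a and alpha cells, a count that ran from 2 (without a/alpha replicate 2) to 26 (without a replicate 1 or alpha replicate 1), and was 5 and 7 without a replicates 2 and 3, 4 and 6 without alpha replicates 2 and 3, and 4 without a/alpha replicate 3.

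The 80, 27, 63 and 26 class members were set against 100 splits of the 9 libraries each, of which 1, 1, 1 and 2 gave as many, with highest other counts of 66, 21, 0 and 34. The splits drawn for all classes together were 265, 265, 268 and 260 different ones, of which 1, 5, 1 and 5 gave as many, the real one included, with highest other counts of 66, 45, 49 and 45. The other splits that gave as many had the 3 a libraries in the distinguished group, and thus counted models higher in a cells. With mixed libraries in that group the highest count was 0 in each class. Of the splits that part all 3 pairs of a and alpha libraries, as the real one does, 1 of 115, 5 of 115, 1 of 117 and 5 of 117 gave as many. These shares lie under 0.05, but splits that mix cell types in the distinguished group gave 0 and fill most of the total. The shares show that libraries of 1 cell type are alike. They cannot exclude chance for the members or the size of a class. Exchanges of a and alpha libraries within numbers allow 8 splits, too few for a share under 0.05 in the a class (63, highest other 26) and the alpha class (26, highest other 63), where both others had all a and alpha libraries exchanged. For the pairwise counts of 652, 517 and 905 the highest of the 9 other splits gave 0 each, whether or not a split parted libraries of the same number, and 10 splits are too few for a share under 0.05, as 1 of 10 is the smallest.

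The first 1 Mb of chromosome C moved as a block. In bins of 200 kb, library medians there ran from -0.55 to 0.79, against -0.19 to 0.23 in 53 bins on other chromosomes. A copy number fixed in each strain, as the whole cause, is argued against by the range within a group, up to 0.97 (log2) among the a libraries. The range does not bear on copy number changes in single cultures, which were not tested. A trend shared by many genes, which this region follows, may contribute: deviations of a replicate 1 and alpha replicate 1 correlated by 0.71 over models outside the region, and GC content was not tested. With the level of the region as a covariate, 71 of the 80 models higher in both haploid types were kept, among them all 13 in it. The region's median log2 fold change against a/alpha cells was -0.15 in a and -0.52 in alpha cells. A shift in that direction would not raise this class, so the covariate is a weak test of it. Of members in the region, the class lower in both kept 4 of 5, the a class 3 of 7 and the alpha class 2 of 2. The block may thus account for some a class members in the region.

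Of 77 pairs of models that overlap on opposite strands, 47 are nested, and the nested models followed their hosts. Over 42 pairs with at least 30 counts each, the median ratio of counts per bp, nested model to host, was 2.11 (quartiles 1.74 and 2.58), with 0 pairs under 0.1 or over 10. A candidate explanation is that reads of both strands were counted, although the kit and the counting are described as stranded. Counting both strands to the same extent would give nested model and host like densities where coverage is even. The nested models mostly lay above their hosts (lower quartile 1.74), so this is not a full account. Whether the strand setting matches the libraries was not tested, and this bears on the counts of all models. Separately regulated antisense transcripts are argued against by the correlation of log2 fold changes of nested model and host, 0.98 over 39 pairs in a against a/alpha cells. The median difference between nested model and host was 0.14 (log2) against 0.41 in random pairs, and no biological explanation was tested beyond this.

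The models lower in both haploid types lay near each other, with 14 pairs within 20 kb, a window set after their positions were seen, against 1.2 on average in 10000 random sets (permutation p = 1e-04, the smallest they can give, adjusted 4e-04 over 4 classes). The pairs involved only 10 of the 27 models: 5 near the end of chromosome A, 3 on chromosome B and 2 elsewhere on chromosome A. Pairs within such a segment are not independent, so the clustering concerns a few places and not the class at large. Leaving out the chromosome C region and overlapping models left 7 pairs against 0.74 (permutation p = 4e-04, adjusted 0.0016), so these do not account for all of the clustering. A single copy number difference spanning a whole segment, as the whole cause, is argued against in the segments from 814917 to 827114 on chromosome A and from 122306 to 141252 on chromosome B. Their models did not change alike (chi-square per degree of freedom at least 15.7, against 99% bounds of up to 3.32). The segments were bounded by members chosen for at least 2-fold changes and include the models between them, which adds to such differences. Copy number changes of single members were not tested. In the segment near the end of chromosome A, from 930346 to 944293, a copy number difference cannot be told apart from regulation, since all 6 models changed alike in a cells (1.29), by -1.22 to -2.68, but not in alpha cells (16.2), where an overlapping pair with uncertain counts was lowest. The models higher in both formed 17 pairs against 11 (permutation p = 0.059, adjusted 0.079), the a class 11 against 6.8 (0.085, adjusted 0.085) and the alpha class 4 against 1.1 (0.03, adjusted 0.06), none past the correction.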

How the results depend on the processing

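Pairwise counts moved by over 1.5 times in 28 of 64 alternatives and class counts in 13 of 88. The settings on the first 1 Mb of chromosome C, on overlapping models and with the a and alpha libraries blocked alone were chosen only after the data were seen. The cause of the shifts was not tested, except that stricter thresholds pass fewer models by construction.

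With the replicate block the counts were 1213 for a against a/alpha (652 without it), 1552 for alpha against a/alpha (517) and 1575 for a against alpha (905). It was 2189 when the a and alpha libraries were blocked alone. For the comparisons with a/alpha cells the libraries share only a number: correlations were 0.10, 0.01 and 0.13 for a and -0.01, -0.03 and 0.16 for alpha libraries, and not every library correlated best with its own number. The block moved no class count by over 1.5 times. With the chromosome C level as a covariate, 1432 and 1375 models passed for a against a/alpha and a against alpha. For alpha against a/alpha, DESeq2 gave 831 and the fit of 2 groups alone 920. At an adjusted p of 0.01 the pairwise counts were 290, 180 and 374, and with at least 2-fold changes 259, 232 and 283. Without a fold minimum the classes held 136, 67, 157 and 124 models, and at 4-fold 32, 7, 15 and 6. The authors' deposited tables gave 423 and 289 at 0.01.

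Leaving out 1 library gave 334 to 1075 models for a against a/alpha, 152 to 1172 for alpha against a/alpha and 427 to 1206 for a against alpha. The classes ranged from 60 to 92 (higher in both), 18 to 43 (lower in both), 55 to 72 (a class) and 15 to 59 (alpha class), and the overlap from 91 to 506. For 54 tests of named models, repeats with median-ratio factors, DESeq2, the block or each library left out kept direction and side of the threshold in 630 cases. The other 18 kept direction and lost the call. They were the chromosome B model from 122306 to 123712, alpha against a/alpha, without alpha replicate 2 or 3 or any 1 a/alpha library (log2 -1.03 to -1.28), and the alpha class models from 472961 to 473335 on chromosome A and from 475936 to 477402 on chromosome C in a against a/alpha cells. These lost it without a/alpha replicate 2 (-0.26 and -0.59 in place of -1.67 and -1.65), with DESeq2, or without a replicate 2 or 3, alpha replicate 2 or a/alpha replicate 1, and the chromosome A model also with the block (-1.41). Of the 80 models, 79 were kept with median-ratio factors, 71 with upper-quartile factors and 80 with DESeq2. Without a/alpha replicate 2, 57 of the 80 were kept, 18 of the 27 lower in both, 50 of the 63 in the a class and 15 of the 26 in the alpha class. With the chromosome C level as a covariate 71, 21, 54 and 16 were kept. The gene list tests and their alternatives were not run, because no model is paired with a gene name. Depth limits a/alpha replicate 1 most, where 3 counts equal 4.04 CPM before TMM scaling.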

Other observations

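The classes and segments described here were chosen after the data were seen. Besides the 4 classes of the report, 16 models were at least 2-fold lower in a cells than in both others, with medians of 10.6 CPM in a, 36.7 in alpha and 47.1 in a/alpha cells. Another 26 were lower in alpha cells than in both others, with medians of 49.9, 16.5 and 64.9 CPM. In each set, 3 models also belong to the 27 lower in both haploid types.

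A segment of chromosome A from 930346 to 944293, which ends 5424 bp before the end of the last model on that chromosome, held 5 of the 27 models lower in both haploid types. Its model from 932882 to 933841 was at 31.2 ± 11.4 CPM in a, 35.0 ± 9.66 in alpha and 115 ± 36.7 in a/alpha cells (SD, n = 3). A segment of chromosome B from 122306 to 141252 held 3 such models. The first, from 122306 to 123712, was at 181 ± 84.9, 202 ± 51.6 and 462 ± 82.6 CPM and lost its call against a/alpha in alpha cells when alpha replicate 2 or 3 or any a/alpha library was left out (log2 -1.03 to -1.28), and the next, from 126269 to 127114, at 2.39 ± 0.32, 7.20 ± 1.87 and 54.1 ± 16.4 CPM.

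The 3 models leading the alpha class were each highest, among the a/alpha libraries, in replicate 2. The chromosome G model from 1048341 to 1050398 was at 26.1, 51.01 and 21.4 CPM in a/alpha replicates 1, 2 and 3. The chromosome C model from 475936 to 477402 was at 2.75, 14.1 and 4.40 CPM, and the chromosome A model from 472961 to 473335 at 23.3, 81.1 and 13.5 CPM.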
